A study of Mus musculus with 14 samples.

How the data were processed

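The series compared liver gene expression among 14 female B6C3F1 mice given corn oil or furan, all of which also drank BrdU before necropsy. Per the labels, RNA of each mouse was labelled with Cy5 and a universal mouse reference RNA with Cy3, and the 2 were hybridised together on an Agilent SurePrint G3 mouse gene expression array. All arrays had the same dye orientation, so any dye effect is shared by all samples and drops out of differences between groups. The groups were 4 control mice, 5 mice at 1 mg/kg and 5 mice at 8 mg/kg, taken from the sample titles and treatment labels. The submitters' design text calls the mice of a group biological replicates and describes a randomized block design.

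The deposited scanner files held, per the file headers, spot intensities read with Feature Extraction 10.7.3.1, with the median pixel intensity of each spot and of its local background in both channels. The same files held processed intensities that the scanner software had background-subtracted and dye-normalized, per the file headers. The authors also deposited a table of normalized values, which proved to be linear ratios of sample over reference: log2 of each column correlated at 0.992 to 0.995 with the log ratios computed here for the same array, with slopes of 1.014 to 1.034. The medians of those columns were 0.9765 to 0.9897, and the direction was Cy5 over Cy3. The normalization behind that table is not given in the sources used here, and the table served as an alternative only.

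Each array had 62976 features, of which 3671 were control spots. Median intensities were corrected with limma's normexp method (offset 50) against the median local background, and log2 ratios were normalized within each array by loess, with control spots given no weight. The design written before the data were examined named the mean spot intensity; the files gave the median, which was used instead. Spots with the scanner's outlier flags were left out, which removed 178 to 336 spots per array, and repeated spots were averaged to 55681 probes. No spot was saturated in either channel.

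The files gave accessions rather than gene symbols. Accessions were matched without version to the RefSeq table of mouse assembly GRCm38.p6, which named 26413 probes and left 29268 without a symbol. That table served for names alone, and no coordinates are given, because the probe positions in the file headers refer to an older build. A probe was tested if it was well above background in the sample channel on at least 4 of the 14 arrays, and 28867 probes passed. Among probes of a gene, the one with the highest mean sample-channel signal stood for the gene, which left 21967 features, 13771 of them with a symbol; 3372 symbols had more than 1 probe past the filter. Features without a symbol were counted as genes and are not named. Probes of close paralogs, such as those of the Gsta, Sult2a and tubulin families, can hybridise with each other's transcripts.

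Sample-channel signal was well above background for 23061 to 29844 probes per array (41.4% to 53.6%), and the number of arrays limits the precision. A gene well above background on no array of a group has only a bound there; where some arrays of a group measured it, the fitted value is given with their number. Such a bound was computed from the mean of normalized sample-channel log2 values of the brighter group and the lowest detected level of the dimmer one, and is open to dye bias, because that lowest level comes from other probes and no dyes were swapped.

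Differences between groups were tested with lmFit and eBayes of limma 3.58.1 (R 4.3.3) on all 14 arrays, with the slide as a fixed block. The 14 arrays lay on 5 slides. Of these, 4 slides held all 3 groups and the last held 1 array at 1 mg/kg and 1 array at 8 mg/kg. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are log2 differences between groups with standard errors (SE) from the same fit. The comparisons were 8 mg/kg against control, 1 mg/kg against control, and 8 against 1 mg/kg. Tables were handled with data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

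Before the data were examined, 33 gene lists of liver pathways, stress responses, cell types and possible contaminating tissues were written from general knowledge. Each list with at least 5 measured genes was tested with limma's camera, which compares a list's genes with all others, at a preset inter-gene correlation of 0.01 and again with an estimated correlation. For each list the genes that passed were also counted with p-values adjusted over the list alone. Adjusted p-values of lists are adjusted over the 33 lists.

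The rule for named genes was also fixed beforehand. It took the 12 largest rises and 12 largest falls at 8 mg/kg against control among genes that passed, were well above background on every array of at least 1 group, and had the same sign in every slide holding both groups. It took 6 and 6 for 8 against 1 mg/kg, the 5 smallest p-values where no gene passed, and up to 4 members of each list with the smallest p at 8 mg/kg.

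The procedure was tested on simulated arrays with the real residual spread and slide effects and 200 changed genes among 21967. Noise was drawn for each gene on its own, so the shares below hold for genes without correlation. For 8 mg/kg against control, 58.2% of genes changed by 0.5 on the log2 scale were found, 98.5% of those changed by 1 and 100% of those changed by 2, and 3.9% of calls were false. For 1 mg/kg against control the shares found were 50.7%, 97% and 100%, with 4.6% of calls false. For 8 against 1 mg/kg they were 68.7%, 95.5% and 100%, with 4.3% of calls false.

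Alternatives covered the slide term, the replicate number, the background correction and normalization, the sample channel alone, the authors' ratios, the filter on dim probes, the probe rule, the arrays in the fit, the variance model, a fold threshold of 1.5, and each array left out in turn. In 1 of the normalization alternatives only the average intensities were scaled between arrays. It leaves the log ratios unchanged, so every call is kept under it by construction. Mice without BrdU were not analysed here, so the effect of BrdU itself was not tested. The gene sets of the bile duct and pancreas tests were redefined after earlier versions had been seen. The earlier sets left out the called genes and held dim ones, with medians of 0.002 (SE 0.048, 18 genes) and -0.081 (SE 0.022, 6 genes). The sets now hold every list member well above background on all arrays. The bile duct outcome depended on the version: the median lay under 0.3 by more than 2 SE in 3 of 4 versions, but not in the one used. The pancreas outcome was the same in all 5. The SEs of both tests take genes as independent. The test of the share of hepatocytes was also replaced after its result was seen. The earlier version set 3 called cell type lists against 3 others (a difference of 0.13, SE 0.036), which took genes as independent and lists chosen by their calls. The test for single arrays that stand apart left out 1 gene, whose result is not reported here.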

Results

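Gene expression was measured in the livers of 14 female B6C3F1 mice, a hybrid laboratory strain used in carcinogenicity testing. Corn oil alone was given to 4 mice, furan at 1 mg/kg body weight to 5 and furan at 8 mg/kg to 5, by gavage for 3 weeks, and tissue was taken 4 h after the last dose. Furan is a small heterocyclic compound that forms in heated food and that hepatic cytochrome P450 oxidises to a reactive dialdehyde. All 14 mice drank bromodeoxyuridine (BrdU), a thymidine analogue that enters newly made DNA, for 5 days before necropsy. Values are log2 ratios of liver RNA over a common reference RNA. Between 23061 and 29844 of 55681 probes per array were well above background in the liver channel.

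Slide and dose were the 2 main sources of variation. The first principal component held 30.7% of the variance and 87% of it lay between slides, with the 3 arrays of slide 3 apart from the rest. The second held 16.7%, of which 85.3% lay between dose groups. Each comparison against control was made with the slide as a block, a choice written beforehand from the submitters' randomized block design. The direction within each of the 4 slides that held control and treated mice is given beside each comparison.

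The first comparison asked what the higher dose of furan changed in liver. Among genes that met the naming rule, the 3 largest rises at 8 mg/kg were those of a conjugating enzyme, a p53 target and a fetal liver protein. Gsta1, which encodes an alpha-class glutathione S-transferase, rose by 3.48 ± 0.36 on the log2 scale (SE, n = 5 against 4; 11.2-fold, adjusted p = 0.000252). Cdkn1a, a cyclin-dependent kinase inhibitor induced by p53, rose by 2.19 ± 0.17 (adjusted p = 2.08e-05), and Afp, which encodes the alpha-fetoprotein of fetal liver, by 1.90 ± 0.13 (adjusted p = 1.05e-05). The 3 largest falls by the same rule were those of the sulfotransferase gene Sult2a2 (-2.62 ± 0.65, adjusted p = 0.0383), of Cyp26b1, which degrades retinoic acid (-1.92 ± 0.40, adjusted p = 0.0193), and of the sulfotransferase gene Sult3a1 (-1.72 ± 0.26, adjusted p = 0.00245).

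In all, 871 of 21967 genes differed between 8 mg/kg and control in limma's test, 578 higher and 293 lower, and 269 of them by at least 1.5-fold. Among the 650 with a symbol, 442 were higher and 208 lower. The 12 named rises and 12 named falls were picked to have the same sign in 4 of 4 slides. The other named rises were those of Jun (1.80 ± 0.27), Tubb2a (1.76 ± 0.23), Cbr3 (1.58 ± 0.20), Gdf15 (1.56 ± 0.17), Fst (1.52 ± 0.20), Gsta2 (2.83-fold), Cxcl10 (1.45 ± 0.19), Ly6d (1.43 ± 0.15) and Ddias (1.31 ± 0.17). Jun is an AP-1 transcription factor, Gdf15 a secreted stress cytokine, Fst the activin antagonist follistatin and Cxcl10 a chemokine. Ddias was well above background on 1 of the 4 control arrays, and its value was 1.04 to 3.19 over 28 alternatives; Elovl3 was well above it on 4 of the 5 arrays at 8 mg/kg. Besides the sulfotransferases and Cyp26b1, the named falls were Derl3 (-1.35 ± 0.33), Lrtm1 (-1.29 ± 0.24), Sdf2l1 (-1.07 ± 0.24), Cpsf4l (-1.03 ± 0.12), Etfbkmt (-1.03 ± 0.15), Nr0b2 (-1.02 ± 0.27), Sdr9c7 (-1.02 ± 0.20), Izumo4 (-0.95 ± 0.13) and Elovl3 (-0.94 ± 0.18). Without the slide in the model 276 genes passed, with only the 9 arrays of these groups 306, with the scanner's processed signals 402, and with the liver channel alone 1330 (695 higher and 635 lower, or 52.3% higher against 66.4%). With 1 array left out 313 (without 8 mg/kg replicate 1) to 843 passed, and Nr0b2, Sult2a2 and Derl3 kept their calls under 6, 14 and 15 of 29 alternatives.

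**Figure D1:**
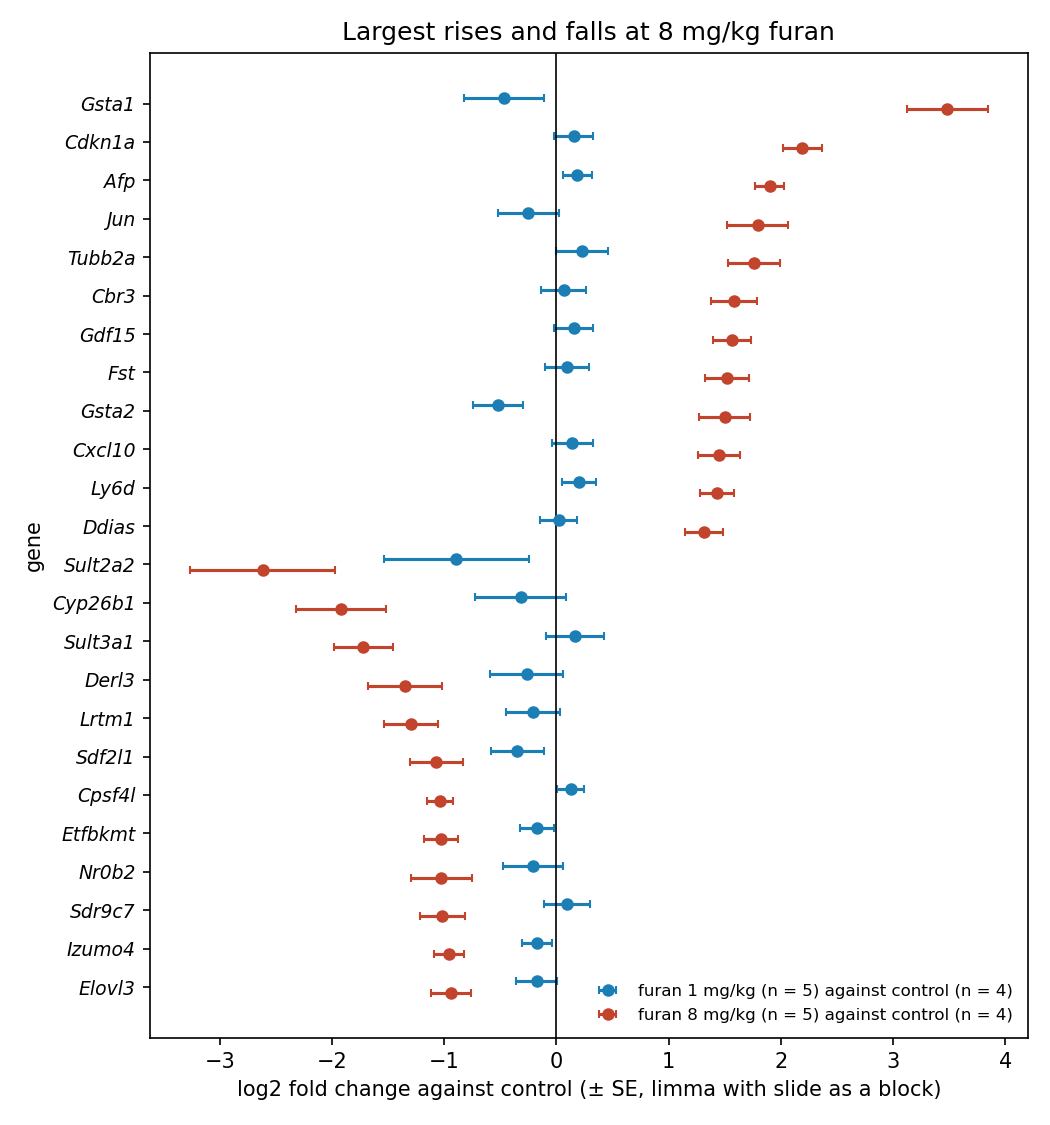
Log2 fold change against control (horizontal axis) of the 24 genes named for 8 mg/kg, with points for 8 mg/kg and for 1 mg/kg and bars of 1 SE from limma with the slide as a block. Gsta1 lies at 3.48 at 8 mg/kg and at -0.47 at 1 mg/kg, where none of the 24 genes passed the test.

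Some genes induced through p53, the transcription factor activated by DNA damage, rose at 8 mg/kg. Of 28 measured p53 targets, 12 rose, 0 fell and 16 did not pass (14 rose and 0 fell when adjusted over the list alone). Aen, an exonuclease, rose by 1.26 ± 0.10 (adjusted p = 2.08e-05), Ccng1 by 1.01 ± 0.10 (adjusted p = 0.000116) and Ddit4l by 0.95 ± 0.10 (adjusted p = 0.000322). Ddit4l was well above background on 1 of 4 control arrays, with values of 0.82 to 2.34 over 28 alternatives, and Tnfrsf10b on 3 of 4. The median of the list was 0.30, higher in 4 of 4 slides (0.27 to 0.47), with a camera adjusted p = 1.51e-11 and an adjusted p = 0.159 with an estimated correlation. In apoptosis regulators, 3 of 29 rose (Tnfrsf10b 0.77 ± 0.10, Tnfrsf12a 1.28 ± 0.17 and Bax 0.65 ± 0.09), 0 fell and 26 did not pass, against 3 that rose and 1 that fell adjusted over the list alone. The list as a whole did not pass (median 0.04, adjusted p = 0.321). Among DNA repair genes 1 of 25 rose, Mgmt, which repairs alkylated guanine (0.48 ± 0.10, adjusted p = 0.0165), and 24 did not pass; 1 rose adjusted over the list alone, and the list lay at -0.01 (adjusted p = 0.712).

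Some targets of NRF2, the regulator of antioxidant and conjugating enzymes, rose as well. Of 37 measured, 14 rose, 0 fell and 23 did not pass (21 rose and 2 fell when adjusted over the list alone). The microsomal epoxide hydrolase gene Ephx1 rose by 0.92 ± 0.08 (adjusted p = 9e-05), Gstm1 by 0.88 ± 0.11 (adjusted p = 0.000732) and the carbonyl reductase gene Cbr3 by 1.58 ± 0.20 (adjusted p = 0.000918). The median was 0.35, higher in 4 of 4 slides (0.08 to 0.68), with a camera adjusted p = 2.12e-12 and an adjusted p = 0.466 with an estimated correlation. Of 25 xenobiotic cytochrome P450 genes 0 passed, with a median of -0.08 (adjusted p = 0.0517); Cyp2j5 lay at -0.52 ± 0.14 (adjusted p = 0.0533), and 0 passed adjusted over the list alone.

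Some immediate early and heat shock genes rose at 8 mg/kg. Of 19 immediate early genes 5 rose and 14 did not pass (6 rose adjusted over the list alone). These included Jun, Myc (1.13 ± 0.17, adjusted p = 0.00211), Klf6 (0.63 ± 0.13, adjusted p = 0.0192) and Gadd45g (0.68 ± 0.16, adjusted p = 0.0304). The list's median was 0.23, higher in 4 of 4 slides (0.17 to 0.27; adjusted p = 0.000666, and adjusted p = 0.613 with an estimated correlation). Of 19 heat shock genes 4 rose (5 adjusted over the list alone) and 15 did not pass, led by the small chaperone gene Hspb1 (1.07 ± 0.19, adjusted p = 0.00792). Their median was 0.25, higher in 3 of 4 slides (-0.06 to 0.42; adjusted p = 0.000228, and adjusted p = 0.613 with an estimated correlation).

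Cell cycle genes were higher at 8 mg/kg in some of the mice. Of 33 genes of DNA replication and S phase 4 rose and 29 did not pass, against 9 that rose and 1 that fell adjusted over the list alone. They were Prim1 (0.69 ± 0.13), the helicase gene Mcm6 (0.87 ± 0.20), Pcna (0.34 ± 0.09) and Cdt1 (0.41 ± 0.11), of which Pcna and Cdt1 kept their calls under 5 and 4 of 29 alternatives. Of 34 mitosis genes 1 rose, the kinetochore gene Spc25 (0.75 ± 0.14, adjusted p = 0.0108), and 33 did not pass; 8 rose adjusted over the list alone. The medians were 0.23 for S phase, higher in 4 of 4 slides (0.06 to 0.40), and 0.23 for mitosis, higher in 3 of 4 (-0.05 to 0.83). Their camera adjusted p-values were 0.000283 and 0.000106, with adjusted p = 0.613 and adjusted p = 0.624 with an estimated correlation. The mean of the mitosis list in the 5 mice at 8 mg/kg was 0.90, -0.28, 0.59, -0.29 and 0.24 around the mean of all arrays. These means also hold slide differences. The controls on the slides of the 2 low mice lay at -0.454 (slide 3) and -0.275 (slide 4), and the slide of the third mouse held no control. Without the first mouse at 8 mg/kg the list no longer passed.

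**Figure D2:**
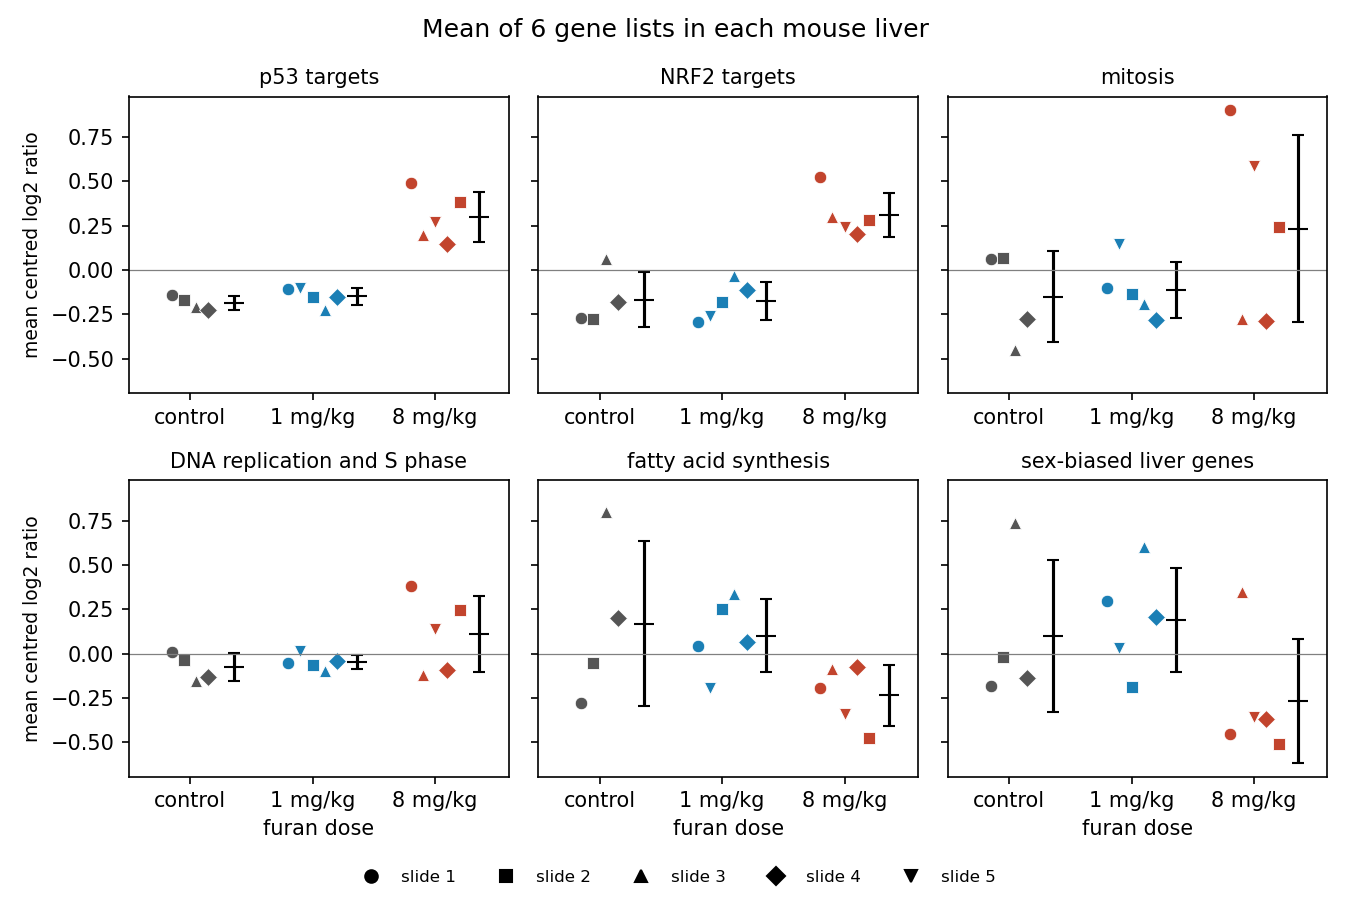
Mean log2 ratio of each of 6 gene lists, centred on the mean of all 14 arrays (vertical axis), in each mouse at 0, 1 and 8 mg/kg, with a marker shape per slide and a bar for the group mean ± 1 SD beside the points (n = 4, 5 and 5). All 5 mice at 8 mg/kg lie above all control mice for p53 and NRF2 targets, and the mitosis list in those 5 mice spans -0.29 to 0.90.

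Genes of lipid synthesis and of the female or male pattern of liver expression lay lower at 8 mg/kg. Of 20 fatty acid synthesis genes 2 fell, 0 rose and 18 did not pass (10 fell adjusted over the list alone). The acetyl-CoA carboxylase gene Acacb changed by -0.88 ± 0.13 (adjusted p = 0.00199) and the pyruvate kinase gene Pklr by -0.57 ± 0.13 (adjusted p = 0.0313). Fasn lay at -0.89 ± 0.26 (adjusted p = 0.0693) and Scd1 at -0.65 ± 0.22 (adjusted p = 0.118). The list's median was -0.34, lower in 3 of 4 slides (-0.94 to 0.09; adjusted p = 4.53e-06, and adjusted p = 0.613 with an estimated correlation). Without control replicate 3 the median was -0.16. Of 25 cholesterol synthesis genes 1 fell, Tm7sf2 (-0.45 ± 0.08, adjusted p = 0.0074), and 24 did not pass; 2 fell adjusted over the list alone. Their median was -0.17, lower in 3 of 4 slides (-0.43 to 0.22; adjusted p = 0.000442, and adjusted p = 0.613 with an estimated correlation). Of 25 sex-biased liver genes 2 fell, Sult3a1 and the elongase gene Elovl3, and 23 did not pass; 6 fell adjusted over the list alone. That median was -0.25, lower in 4 of 4 slides (-0.34 to -0.10; adjusted p = 0.000228, and adjusted p = 0.613 with an estimated correlation).

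These 9 of 33 lists passed camera at the preset correlation and 0 with an estimated one. Of 100 splits of the control and 8 mg/kg arrays, the real one included, 53 gave at least 9 lists. A p as small as the real one came up in 1 of the 100 splits for p53 targets and in 2 for NRF2 targets, but in 9 to 42 for the other 7 lists. These counts per list were chosen after the results were seen. The splits also did not keep the slide blocks, so the counts do not exclude chance for any list.

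Endoplasmic reticulum (ER) stress genes moved in both directions. Of 28 measured, 3 rose, 2 fell and 23 did not pass (5 rose and 10 fell adjusted over the list alone), and the list did not pass (median -0.15, adjusted p = 0.062). The transcription factor genes Atf4 (0.64 ± 0.14, adjusted p = 0.0249) and Atf3 (1.11 ± 0.27, adjusted p = 0.0383) rose. The oxidoreductase gene Ero1b (-0.86 ± 0.15, adjusted p = 0.0069) and Sdf2l1, part of an ER chaperone complex (adjusted p = 0.0244), fell. Among PPARA targets and fatty acid oxidation genes 3 of 32 rose (7 adjusted over the list alone) and 29 did not pass. They were the lipid droplet gene Cidec (1.30 ± 0.26, adjusted p = 0.0137), Pdk4 (0.84 ± 0.20, adjusted p = 0.031) and Acot2 (0.63 ± 0.15, adjusted p = 0.0352), and the list lay at 0.08 (adjusted p = 0.062). In bile acid synthesis and transport 1 of 25 rose, the uptake transporter gene Slc10a1 (0.40 ± 0.10, adjusted p = 0.0448), and 1 fell, the nuclear receptor gene Nr0b2, with 23 not passing (1 rose and 3 fell adjusted over the list alone; median -0.11, adjusted p = 0.0912). Slc10a1 kept its call under 7 of 29 alternatives.

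**Figure D3:**
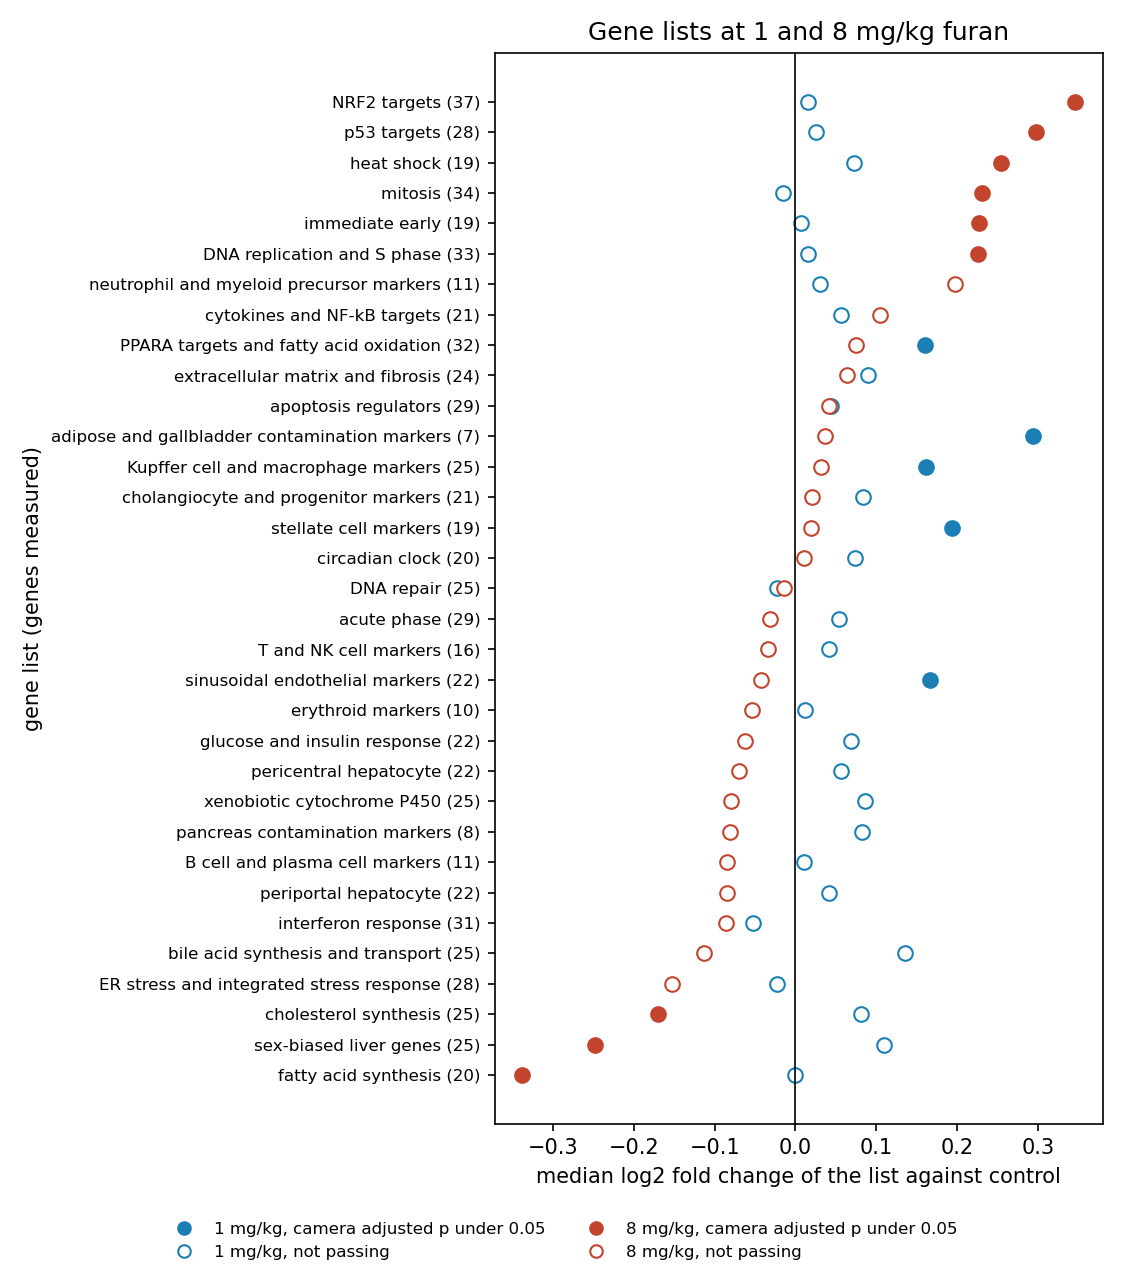
Median log2 fold change against control (horizontal axis) of the measured genes of each of 33 lists at 1 mg/kg and 8 mg/kg, with the number of genes in brackets and filled points for a camera adjusted p under 0.05 at the preset correlation. NRF2 targets lie at 0.35 at 8 mg/kg and at 0.02 at 1 mg/kg.

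Markers of inflammation and of other liver cells changed in few members at 8 mg/kg. Of 21 cytokines and NF-kB targets, Cxcl10 and Vcam1 (0.54 ± 0.11, adjusted p = 0.0158) rose, Il18 fell (-0.43 ± 0.09, adjusted p = 0.0217) and 18 did not pass (2 rose and 1 fell adjusted over the list alone; median 0.10, adjusted p = 0.0793). Of 29 acute phase genes 2 rose, Cd14 (0.44 ± 0.10) and Cp (0.39 ± 0.10), 1 fell, Orm2 (-0.39 ± 0.10), and 26 did not pass (2 rose and 3 fell adjusted over the list alone). That list's median was -0.03, its mean 0.004 and its test pointed down (adjusted p = 0.713). Of 31 interferon response genes 1 fell, Irf7 (-0.45 ± 0.11, adjusted p = 0.0307; 1 also adjusted over the list alone), and the median was -0.09 (adjusted p = 0.0793). Of 21 cholangiocyte and progenitor markers 3 rose, Prom1 (1.24 ± 0.15, adjusted p = 0.00075), Krt18 (0.58 ± 0.09, adjusted p = 0.00284) and Krt23 (0.87 ± 0.22, adjusted p = 0.042), and 18 did not pass (4 rose adjusted over the list alone). The median of that list was 0.02 (adjusted p = 0.184), and Krt23 kept its call under 7 of 29 alternatives.

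Of 25 Kupffer cell and macrophage markers 1 rose, the cathepsin gene Ctss (0.39 ± 0.10, adjusted p = 0.0482), and 24 did not pass (2 rose adjusted over the list alone; median 0.03, adjusted p = 0.184). Markers of stellate cells (19 genes), sinusoidal endothelium (22), T and NK cells (16), B and plasma cells (11) and neutrophils and myeloid precursors (11), and extracellular matrix genes (24), had 0 members that passed, over all genes or adjusted over the list alone. Their medians were 0.02, -0.04, -0.03, -0.09, 0.20 and 0.06. Of 22 pericentral hepatocyte genes Slc1a2 (-0.38 ± 0.09) and the glutamine synthetase gene Glul (-0.35 ± 0.09) fell and 20 did not pass (1 rose and 3 fell adjusted over the list alone), with a median of -0.07 (adjusted p = 0.171). Of 22 periportal genes the carbamoyl phosphate synthetase gene Cps1 fell (-0.34 ± 0.08, adjusted p = 0.0346; 1 also adjusted over the list alone), with a median of -0.09 (adjusted p = 0.062).

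Among markers of tissue that could have been dissected with liver, 1 of 8 pancreas genes fell, the amylase gene Amy2a5 (-0.73 ± 0.11, adjusted p = 0.00235), while Cela2a, well above background on 1 of 4 control arrays and 1 of 5 at 8 mg/kg, lay at -0.12 ± 0.09 and Ctrb1 at -0.09 ± 0.09. The pancreas list lay at -0.08 (adjusted p = 0.0849; 1 fell adjusted over the list alone). Of 7 adipose and gallbladder genes 1 rose, the lipoprotein lipase gene Lpl (0.96 ± 0.19, adjusted p = 0.0146; 1 also adjusted over the list alone), with a median of 0.04 (adjusted p = 0.321). Of 10 erythroid genes 1 rose, the carbonic anhydrase gene Car2 (1.13 ± 0.13, adjusted p = 0.000365; 1 also adjusted over the list alone), while the globin genes Hbb-bt and Hba-a2 lay at -0.14 ± 0.09 and 0.10 ± 0.09. That list's median was -0.05, its mean 0.08 and its test pointed down (adjusted p = 0.992).

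The next comparison asked what the lower dose changed. At 1 mg/kg no gene passed limma's test against control (0 of 21967, n = 5 against 4, smallest adjusted p = 0.0578), and 1510 genes (6.87%) had an unadjusted p under 0.05. The 5 named genes with the smallest p were Impg2 (0.61 ± 0.10, unadjusted p = 4.28e-05 in limma), Cdcp2 (0.85 ± 0.15), Clca3a1 (0.40 ± 0.08), Slc44a3 (0.48 ± 0.10) and Ucn3 (0.50 ± 0.11), none of which passed. Cdkn1a lay at 0.16 ± 0.17, Afp at 0.19 ± 0.13, Ccng1 at 0.23 ± 0.10 and Ephx1 at 0.27 ± 0.08, and Gsta1 and Gsta2 lay below control at -0.47 ± 0.36 and -0.52 ± 0.23. The medians of p53 and NRF2 targets were 0.03 and 0.02 (adjusted p = 0.856 for each), with the NRF2 list's test pointing down. That test also pointed down, against a median of 0.02 for S phase, 0.06 for cytokines, 0.007 for immediate early genes, 0.01 for B cells and 0.01 for erythroid markers, none of which passed. With 1 array left out 0 to 3 genes passed, and 1 passed without background correction, with the authors' ratios and without the filter on dim probes.

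Gene lists were tested at 1 mg/kg as well. In each of the 33 lists 0 genes passed, and 2 PPARA targets, 3 acute phase genes, 2 Kupffer cell markers and 1 adipose marker rose when adjusted over the list alone. Camera placed 5 lists higher at the preset correlation: PPARA targets (median 0.16, adjusted p = 0.000363), stellate cell markers (0.19, adjusted p = 0.000363), sinusoidal endothelial markers (0.17, adjusted p = 0.000363), Kupffer cell markers (0.16, adjusted p = 0.00752) and adipose and gallbladder markers (0.29, adjusted p = 0.0439). Each had adjusted p = 0.924 with an estimated correlation, and 0 lists passed with the scanner's processed signals. Of 100 splits of these arrays, the real one included, 74 gave at least 5 lists, and the median of the others was 7. Within the 4 slides the PPARA, endothelial, Kupffer and adipose lists were higher in 3 and the stellate list in 2. Cfd, an adipocyte gene, was not well above background on any control array. It was well above background on 3 of 5 arrays at 1 mg/kg and on 1 of 5 at 8 mg/kg, and passed at neither dose. At 8 mg/kg it was at least 1.65-fold higher than in controls, and no such bound was computed at 1 mg/kg. Periportal and pericentral hepatocyte genes lay at 0.04 and 0.06.

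The last comparison set the 2 doses against each other. Livers at 8 mg/kg differed from those at 1 mg/kg in 1143 genes of 21967 (limma, n = 5 against 5), 518 higher and 625 lower, and in 269 by at least 1.5-fold. The largest named rises were Gsta1 (3.95 ± 0.33, adjusted p = 3.62e-05), Jun (2.05 ± 0.25), Cdkn1a (2.04 ± 0.16), Gsta2 (2.02 ± 0.21), Afp (1.71 ± 0.12) and Tubb2a (1.53 ± 0.21). The largest named falls were Sult3a1 (-1.89 ± 0.24, adjusted p = 0.000754), Cyp26b1 (-1.60 ± 0.37), the apoptosis gene Bmf (-1.34 ± 0.27), the organic anion transporter gene Slco1a1 (-1.23 ± 0.20), Cpsf4l (-1.16 ± 0.11) and S1pr5 (-1.14 ± 0.19). Without the slide in the model 297 genes passed, with the scanner's processed signals 430 (277 higher and 153 lower, or 64.4% higher against 45.3%), and with 1 array left out 418 (without 8 mg/kg replicate 1) to 1242.

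Of p53 targets 14 of 28 rose and 0 fell between the doses (median 0.40, higher in 5 of 5 slides; 17 rose and 3 fell adjusted over the list alone; adjusted p = 1.79e-13, and adjusted p = 0.105 with an estimated correlation). Of NRF2 targets 17 of 37 rose and 0 fell (median 0.35, higher in 5 of 5 slides; 19 rose adjusted over the list alone; adjusted p = 5.94e-15, and adjusted p = 0.293 with an estimated correlation). Sex-biased genes fell in 6 of 25 members (median -0.34, lower in 5 of 5 slides; 9 adjusted over the list alone; adjusted p = 2.57e-07, and adjusted p = 0.293 with an estimated correlation). Fatty acid synthesis genes fell in 4 of 20 (median -0.36, lower in 5 of 5 slides; 7 adjusted over the list alone) and cholesterol synthesis genes in 3 of 25 (median -0.28, lower in 5 of 5 slides; 10 adjusted over the list alone). Their adjusted p-values were 1.14e-05 and 1.47e-05, and adjusted p = 0.457 for each with an estimated correlation. Sinusoidal endothelial markers lay at -0.23, lower in 5 of 5 slides, with 1 of 22 falling (3 adjusted over the list alone; adjusted p = 1.14e-05, and adjusted p = 0.457 with an estimated correlation). Mitosis genes lay at 0.32, higher in 3 of 5 slides, with 1 of 34 rising (8 adjusted over the list alone; adjusted p = 5.46e-10, and adjusted p = 0.457 with an estimated correlation). Camera at the preset correlation also placed S phase, immediate early, heat shock and cytokine genes higher, with medians of 0.17, 0.21, 0.16 and 0.13. It placed cytochrome P450, bile acid, pancreas, stellate, periportal and pericentral genes lower, with medians of -0.14, -0.22, -0.16, -0.12, -0.12 and -0.09. None of these passed with an estimated correlation (smallest adjusted p = 0.293 with an estimated correlation, for immediate early genes). Apoptosis regulators, clock genes, cholangiocyte markers and erythroid markers had medians of -0.05, -0.10, -0.02 and -0.02 while their tests pointed up, and none passed.

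Genes changed at 8 mg/kg lay mostly on the same side of control at 1 mg/kg, but comparisons that share control mice do so by chance as well. Of the 871 genes, 685 (78.6%) had the same sign at 1 mg/kg, with a median log2 change in that direction of 0.46 at 8 mg/kg and 0.10 at 1 mg/kg. Simulated groups unchanged at both doses, set against the same controls, gave 95.2% for their top genes. Noise in the shared controls, which gives both doses the same sign, selects such top genes. The 871 genes also hold changes at 8 mg/kg, so these draws do not give the share to expect without a change at 1 mg/kg. Over 21967 genes, which are not independent replicates, the fold changes at the 2 doses correlated at r = 0.351 with a covariance of 0.0094, and simulated unchanged groups gave r = 0.579 and a covariance of 0.0084, a difference of 0.001. Rotated residuals, a second way to draw unchanged groups, gave a covariance of 0.0074 with a 95th percentile of 0.0177, r of -0.147 to 0.903 (5th to 95th percentile) and a mean same-sign share of 87.2%. The observed r and covariance lay below those upper percentiles, while the highest covariance among the simulated groups was 0.009. Changes at 8 mg/kg alone would lower r as well, so neither the shares nor the r values decide whether the doses agree. With 2 controls for each dose, r over the 6 assignments was -0.19 to 0.08 and the same-sign share 41.2% to 60%. These differences were taken without the slide block, and the 2 pairs of controls lay on different slides. Slide differences between the pairs enter the 2 doses with opposite signs and can lower r and the share. For that reason these values do not decide it either. At 8 mg/kg, 294 genes were higher and 230 lower against both control and 1 mg/kg. Those comparisons share the arrays at 8 mg/kg, and independent lists of these lengths would share 13.6 and 8.34 genes, which are not the values expected without a change when arrays are shared.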

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

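The tests of bile duct cells, pancreas tissue, control replicate 3, the share of hepatocytes and a single mouse at 1 mg/kg were chosen after the results they bear on were seen; the others were set before. Values below are the difference of 1 array from the mean of the others of its group, on the log2 scale, where its gap to the nearest other array was large for the range of the group.

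Such gaps were found in 43 of 561 groups of values, where chance gives about 1 in 20 groups, or 28. Slide 3 held 27 of the 43, and slides 1, 2, 4 and 5 held 2, 6, 3 and 5. Gaps came up in 29 of 450 groups of single genes (22.5 by chance) and in 14 of 99 groups of list means (5 by chance). None came up in the 12 groups of array measures.

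Control replicate 3, on slide 3, lay above the other controls by 1.08 for Cpsf4l, 0.45 for Gadd45g, 1.24 for Orm2, 1.16 for Etnppl, 0.21 for Lyz1, 0.84 for Lrat and 1.22 for Lcn2, and differed by -0.13 for Prf1. Its list means were higher by 0.94 for cytochrome P450, 0.99 for acute phase, 0.84 for periportal genes, 0.59 for glucose and insulin response and 0.40 for sinusoidal endothelial markers. Replicate 2 at 8 mg/kg, on the same slide, was higher by 0.57 for Hgf, 0.87 for Fpr2 and 0.52 for Cd22. Its list means were higher by 0.85 for cytochrome P450, 0.65 for acute phase, 0.34 for interferon response, 0.77 for sex-biased genes, 0.51 for glucose and insulin response, 0.30 for stellate markers and 0.58 for erythroid markers. Replicate 4 at 1 mg/kg, also on slide 3, differed by 0.64 for Cpsf4l, -0.39 for Bax, 0.75 for Cp and 0.77 for Orm1.

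On the other slides, replicate 2 at 1 mg/kg differed by -0.39 for Aen, 0.35 for Klf6, 0.58 for Ctrb1, 0.55 for Nek2 and -0.54 for Prtn3, with Prtn3 well above background on 4 of 5 arrays at 1 mg/kg. Replicate 3 at 1 mg/kg differed by -1.09 for Cyp26b1 and replicate 5 by 0.23 for Ifi44. Control replicate 1 differed by 0.08 for Tlr2, control replicate 2 by -0.27 for Irs1 and control replicate 4 by -0.58 for Cela1. At 8 mg/kg, replicate 5 differed by -0.28 for Acacb, 0.56 for Cdt1, 0.63 for Acot2 and 3.60 for Cfd. Cfd was well above background on 1 of 5 arrays at 8 mg/kg, so the 3.60 rests on signal near background in the other 4. The circadian list mean of replicate 1 differed by -0.27 and the B cell list mean of replicate 4 by -0.31.

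The reference channel, which held the same RNA on every array, gave 1 gene between 8 mg/kg and control (Abcc6, -0.55 ± 0.06, adjusted p = 0.0281 in limma), 1 gene between 8 and 1 mg/kg (Cyp2b13, -0.58 ± 0.06, adjusted p = 0.0323) and 0 between 1 mg/kg and control, with 933, 812 and 259 genes at an unadjusted p under 0.05. Neither gene passed in the log ratios (-0.21 and -0.37). These 2 genes were named after their values were seen. The unadjusted counts are each under 1 in 20 of the 21967 genes. The rule set beforehand concerned 8 mg/kg against control alone, and with 1 gene there a difference in the reference RNA or its labelling between groups was not excluded. Of the 871 genes of that comparison, 0 passed in the reference channel. The sample channel alone, which does not use the reference, also called 668 of them, which argues against a reference difference as the source of those 668.

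Afp, of fetal liver, and Prom1, Krt23 and Krt18, members of the list of cholangiocyte and progenitor markers, were higher at 8 mg/kg (1.90, 1.24, 0.87 and 0.58). Prom1 lay at 0.41 and did not pass with the scanner's processed signals. Membership of that list does not make a gene specific to bile duct cells. More bile duct cells stay open as a source: the 15 bile duct markers well above background on all arrays had a median of 0.087 (SE 0.129), Prom1, Krt23 and Krt18 included, and the 12 others 0.029 (SE 0.065). A return of fetal liver genes remains open: 7 measured genes had a median of 0.088 (SE 0.166), with Spink1 at 0.72 (adjusted p = 0.00847 in limma) and Dlk1 at -0.33. A change of hepatocyte state with furan may explain the rise and was not tested.

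Fatty acid synthesis genes and 14 ER folding genes had medians of -0.34 and -0.52 at 8 mg/kg. Of the 14, 3 passed, and that set had no test of its own. The ER stress list did not pass (camera adjusted p = 0.062). The set held members of that list without Atf4 and Atf3, which rose. It also held Derl3 (-1.35), a named fall from outside the list, so its median does not stand for the list. For pancreas tissue in the controls, the 6 pancreas genes well above background on all arrays, Amy2a5 (-0.73) included, had a median of -0.065 (SE 0.144). They fell less than the ER folding genes, by a difference of 0.46 (SE 0.18), which depends on the genes chosen for that set. These SEs take genes of the same mice as independent, and the pancreas list was lower in 4 of 4 slides (-0.18 to -0.01). Pancreas tissue is therefore not excluded. Lower food intake would raise genes induced by fasting, and 8 such genes outside the fixed lists had a median of -0.174 (SE 0.096); it stays open, because that set left out Pdk4, Cidec, Acot2 and Igfbp1 (1.10), whose rises go with it. Control replicate 3 as the source stays open for the fatty acid list, whose median moved from -0.34 to -0.16 without that array. The list still passed camera at the preset correlation (adjusted p = 0.00118). That call cannot decide it, because 20 of 100 splits gave a p as small as that of all arrays. An effect of furan could explain the fall and stays open, with the list's loss of its call under an estimated correlation.

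The lists higher at 1 mg/kg could reflect a lower share of hepatocytes, which would raise markers of all other cell types alike. It stays open. In 8 lists of other cell types, over the members well above background on all arrays alone, medians ran from -0.02 (B cells, 7 genes) to 0.19 (stellate cells). Those medians had a standard deviation of 0.082, and 27 of 100 splits of the arrays gave as large a spread (highest other 0.153). Dependence on 1 mouse at 1 mg/kg remains open: without replicate 5 only 2 of the 5 lists passed, and without each of the other 4 mice all 5 did. A response to the low dose is a hypothesis that these data leave open, since 74 of 100 splits of the arrays gave as many lists.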

How the results depend on the processing

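Leaving out slide 3 and leaving out slide 5 were chosen after the data were seen; all other alternatives were set before. Counts below are of genes for 8 mg/kg against control (871) and 8 against 1 mg/kg (1143), and the cause of a change was not tested unless stated. They were 276 and 297 without the slide, 402 and 430 with the scanner's processed signals and 269 and 269 at 1.5-fold or more, which by construction keeps part of the same calls. For 8 mg/kg against control the count was 306 with only the arrays compared, fewer arrays by construction, and 1330 with the sample channel alone, which shared 668 genes with the 871. Without slide 3 it was 395, and without slide 5 the counts were 536 and 528. Slide 5 held only replicate 2 at 1 mg/kg and replicate 3 at 8 mg/kg. With the slide as a block, leaving out either of these arrays is the same fit as leaving out slide 5.

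With a replicate block in place of the slide 121 and 149 genes passed. The replicate numbers did not pair the samples: 5 of 13 same-number pairs correlated above 0.1 and 3 of 14 samples correlated best with their own number, against 10 of 14 with their own slide.

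For 1 mg/kg against control (0 genes), 1 gene passed without background correction, 1 with the authors' ratios and 1 without the filter on dim probes, the same feature each time, with no symbol here. With 1 array left out the counts were 0 to 3 for 1 mg/kg against control, 313 to 843 for 8 mg/kg against control and 418 to 1242 for 8 against 1 mg/kg. The 3 came without 1 mg/kg replicate 3 and included Cdcp2 (1.03, adjusted p = 0.0178 in limma); 1 gene passed without 8 mg/kg replicate 5. For 8 mg/kg against control, 327, 416, 362 and 527 passed without control replicates 1, 2, 3 and 4, 536 without 1 mg/kg replicate 2, and 313, 536 and 387 without 8 mg/kg replicates 1, 3 and 5. For 8 against 1 mg/kg, 471, 528, 726 and 728 passed without 1 mg/kg replicates 1, 2, 3 and 5, and 418, 528 and 610 without 8 mg/kg replicates 1, 3 and 5.

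Of lists, 5 passed at 1 mg/kg and 9 at 8 mg/kg against control, and 0 and 0 with an estimated correlation. At 1 mg/kg 3 passed with the slide as a random block, 2 with the replicate block, 0 with the scanner's processed signals, 8 without the filter on dim probes and 8 without slide 3. At 8 mg/kg 16 passed with the sample channel alone and 14 without the filter. With 1 array left out 4 to 13 passed at 1 mg/kg (13 and 9 without 1 mg/kg replicates 3 and 4) and 9 to 18 at 8 mg/kg (18 without control replicate 4, 15 without 8 mg/kg replicate 4).

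The correlation of fold changes at the 2 doses (0.351) was -0.19, 0.082, -0.168, 0.046, -0.119 and -0.053 with control replicates 1 and 2, 1 and 3, 1 and 4, 2 and 3, 2 and 4, and 3 and 4 set against 1 mg/kg and the other 2 against 8 mg/kg, where no control array is shared by construction.

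Of 4335 values of named genes at 8 mg/kg against control under alternatives, 3683 kept their side of the threshold, 590 no longer passed, 62 newly passed and 0 reversed. The values kept include those under the scaling of average intensities, which changes no log ratio. Of 4335 at 1 mg/kg 4334 kept it and 1 newly passed, and of 348 for 8 against 1 mg/kg 328 kept it and 20 no longer passed. Signal over background limits genes not well above it on every array, such as Ddias and Cfd.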

Other observations

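The per-list counts of splits below were chosen after the results were seen; the splits for genes and for numbers of lists were set before. Of 22 glucose and insulin response genes at 8 mg/kg, Igfbp1, which encodes an insulin-repressed binding protein of growth factors, rose by 1.10 ± 0.21 (limma, n = 5 against 4, adjusted p = 0.0125). Pfkfb1, a bifunctional enzyme of glycolysis control, changed by -0.60 ± 0.14 (adjusted p = 0.0304), and 20 did not pass (2 rose and 2 fell adjusted over the list alone). That list's median was -0.06, its mean 0.009 and its test pointed down (adjusted p = 0.609). Of 20 circadian clock genes Clock rose by 0.61 ± 0.16 (adjusted p = 0.0448), higher in 3 of 4 slides, and 19 did not pass (2 rose adjusted over the list alone). Arntl, its partner, well above background on 3 of 4 control arrays, lay at 0.95 ± 0.25 (adjusted p = 0.0514), and the list lay at 0.01 (adjusted p = 0.766).

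Splits of the same arrays into groups of the same sizes were drawn 100 times per comparison, the real split included. Arrays were exchanged between slides, so these splits did not keep the slide blocks of the design. For 8 mg/kg against control only the real split gave as many as 871 genes, 1 of 100, and the highest other gave 499. The splits with 499 and 264 genes set the 4 controls and 1 array at 8 mg/kg against the other 4 at 8 mg/kg, so they nearly turn the real contrast over. For 8 against 1 mg/kg only the real split gave as many as 1143 genes, 1 of 100, with 31 as the highest other. The slide stayed a block in each fit, and splits less balanced on the slides than the real one find fewer genes by construction. For that reason the splits do not exclude chance for the counts of 871 and 1143. For 1 mg/kg against control the real count was 0, so all 100 of 100 splits gave as many by necessity, which says nothing about chance; the highest other gave 20.

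Chance was not excluded for the number of lists: 53 of 100 splits gave at least the 9 lists found at 8 mg/kg, with 16 as the highest other, and 74 of 100 gave at least the 5 found at 1 mg/kg, with 17 as the highest other. For single lists at 8 mg/kg, a p as small came up in 1 of 100 splits for p53 targets and in 2 for NRF2 targets. At 1 mg/kg it came up in 19 for PPARA targets, 14 for stellate, 12 for endothelial, 30 for Kupffer cell and 4 for adipose and gallbladder markers. Because the splits did not keep the slide blocks, these counts do not exclude chance for any single list.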
